A study of Mus musculus with 9 samples.

How the data were processed

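Liver lymphatic endothelial cells were sorted from IL7-GFP knock-in mice at 2 or 4 weeks after bile duct ligation or after sham surgery, with 3 mice per group per the series' design text. Per the labels' protocols, 20000 to 50000 cells per sample went directly into TRIzol, total RNA was extracted and libraries were made after depletion of ribosomal RNA. The gate used for sorting was not given in the sources used here. Per the submitters' processing notes, the tools were Trim Galore 0.5.0, HISAT2 2.1.0, StringTie 1.3.3b and DESeq2 1.22.1 with the mouse build mm10; their order and settings, the annotation release and whether counting used strand were not given in the sources used here.

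The deposited table held a normalized signal, that is gene counts divided by 1 size factor per library, for 21936 rows, all of them protein-coding genes per the table. In each column the values were whole multiples of the smallest value above 0, and 100.0% of 197424 values were whole reads within a tolerance of 0.001 after division by it. Whole reads recovered in this way ranged from 592419 in sham replicate 2 to 5314381 in 2-week replicate 1, and the other 8 libraries had at least 2259239. These are counted reads on the protein-coding genes of the table, called depth here. Reads that fell elsewhere are not in them, so they do not give the number of reads sequenced. A count of 0 allows up to 3 reads, which was 15.8 normalized counts in sham replicate 2 and between 1.77 and 3.69 in the other libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. All 9 sample columns were matched to labels by name. Symbols were those of the table; 67 rows shared a symbol with another row and were told apart by gene ID. Of the gene IDs, 21894 were found in GENCODE release M21 (GRCm38, the same assembly as mm10), 21516 with the same symbol, and coordinates were taken from it.

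Since the values are normalized rather than raw counts, the main test was limma 3.58.1 in R 4.3.3 on log2(normalized count + 1), with a mean for each of the 3 groups over all 9 libraries (6 residual degrees of freedom), empirical Bayes moderation with a trend, two-sided tests and Benjamini-Hochberg adjustment over the 11809 genes with a mean of at least 10 normalized counts; 10127 genes lay below it. Genes with an adjusted p below 0.05 are said to have passed. Sham, 2 weeks and 4 weeks of ligation were compared in 3 contrasts. Gene lists of cell types and pathways, 40 in all, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists; 35 had at least 5 members among the tested genes. The lists for mesothelial cells, T and NK cells, B and plasma cells, erythroid cells and platelets, and histones had fewer and were not tested. The 40 lists, the tests, the rule for named genes and the alternatives other than those said below to be chosen later were fixed before the data were examined.

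Named genes were, per contrast, the 10 with the largest rise and the 10 with the largest fall among genes that passed, had a mean of at least 50 normalized counts, a symbol that is not a predicted model, and no overlap between the libraries of the 2 groups; up to 4 members with the lowest p from each list described; and a fixed set of endothelial and other cell markers with Il7. Where none passed, the 5 lowest p per direction were named and said not to have passed. Groups did not overlap for 17.9%, 17.0% and 9.40% of the tested genes in the 2-week, 4-week and 4-against-2-week contrasts, against 10% by chance; 108 genes met every condition at 4 weeks.

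Alternatives were other pseudocounts and filters, TMM and quantile scaling, fits with only the groups compared, with the replicate number as a block or with library quality weights, edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, camera with an estimated correlation, fry, and leaving out each library. Chosen after seeing the data were the fits without sham replicate 2 and 4-week replicate 1 together, with the mean log2 level of macrophage markers as a covariate, and with edgeR without sham replicate 2, as well as 3 lists of macrophage markers and the simulation of genes picked on the 4-week contrast, in which all 3 groups had the same means and the spread of these libraries. Replicate libraries differed beyond sampling noise in every pair of the same group, with a chi-square per degree of freedom of 7.26 to 50.9, so none was a repeat deposit.

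The procedure was tested on simulated counts with the means, depths and dispersions of these libraries, in which 200 genes were changed. For 4 weeks against sham, over 11635 genes passing the filter, limma called 7 of 67 genes changed by 2-fold, 30 of 64 changed by 4-fold and 55 of 65 changed by 8-fold in the right direction, with 3 calls among unchanged genes. For 2 weeks against sham, over 11611 genes, it called 7 of 66, 46 of 67 and 55 of 62, with 6 such calls, and for 4 against 2 weeks, over 11628 genes, 3 of 66, 41 of 65 and 51 of 64, with 6. DESeq2 made 29, 17 and 38 calls among unchanged genes at 2 weeks, 4 weeks and between them. Unchanged genes had 1 mean in all simulated libraries and were drawn independently, so no simulated library deviated as a whole. Library quality weights called 45 of 67 genes changed by 4-fold at 2 weeks there, close to limma without weights. In the data they raised the 2-week calls from 2 to 1112. The simulated rates therefore need not hold for these libraries. In each of the 3 contrasts camera called the shifted list and 0 of 40 unshifted lists. Genes were drawn independently there, so the unshifted lists had no inter-gene correlation. In the data the estimated correlation was 0.494 for the interferon list and 0.630 for antigen presentation. The simulation therefore does not test false list calls at such correlations. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.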

Results

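RNA was sequenced from lymphatic endothelial cells sorted from the livers of mice that had undergone bile duct ligation (BDL), a surgical model of cholestasis in which bile cannot leave the liver, or a sham operation. The cells came from IL7-GFP knock-in mice, in which green fluorescent protein is expressed from the Il7 locus and marks lymphatic endothelium. There were 3 sham libraries, 3 libraries from mice at 2 weeks of ligation and 3 from mice at 4 weeks of ligation. The time between sham surgery and collection was not given in the sources used here. Whole reads recovered from the normalized counts came to 3324445, 592419 and 3717921 in sham replicates 1, 2 and 3. They came to 5314381, 4450196 and 4366401 at 2 weeks and to 4399759, 3010049 and 2259239 at 4 weeks. One read was worth 5.26 normalized counts in sham replicate 2 and between 0.589 and 1.23 in the other 8 libraries, so that low genes were measured least precisely in that library.

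The libraries carried lymphatic endothelial transcripts together with transcripts of other liver cells. Prox1, the transcription factor that specifies lymphatic endothelium (ENSMUSG00000010175, chromosome 1, 190118035 to 190170714 of GRCm38), was at 1419.9 ± 982 normalized counts in sham, 1129 ± 477 at 2 weeks and 1252 ± 699.7 at 4 weeks (SD, n = 3 each). Lyve1, a hyaluronan receptor of lymphatic and sinusoidal endothelium, was at 2229 ± 1441, 4702 ± 2692 and 6002 ± 1909.8, and Flt4, the receptor of VEGF-C, at 4683 ± 3430.3, 3928 ± 1869.5 and 4474 ± 1555. Pdpn was at 139 ± 74.6, 180.4 ± 63.5 and 202 ± 109, Pecam1 at 1411 ± 645, 1386 ± 463 and 1354 ± 353, and Cdh5 at 3653 ± 461, 2969 ± 151 and 2247 ± 529. Il7, the reporter locus, was at 49.97 ± 29.9, 50.9 ± 19.4 and 43.5 ± 21.4. None of these genes passed the test in limma in any contrast, and 0 of the 15 measured members of the lymphatic endothelial identity list passed at 2 weeks, 4 weeks or between them. The 2 rows named Ccl21a held a single read over all libraries, and reads of this gene are shared with near-identical copies, so its level is uncertain.

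Markers of macrophages were among the abundant transcripts. Clec4f, a lectin of Kupffer cells, stood at 10215 ± 3463 normalized counts in sham, 7.19 times the level of Prox1 there. Without sham replicate 2, in which Prox1 was lowest, the ratio was 4.28. Ptprc, the pan-leukocyte gene for CD45, was at 1732 ± 359 in sham, 1535 ± 406 at 2 weeks and 1266 ± 771 at 4 weeks. The hepatocyte gene Alb was at 4534 ± 3849.8, 3867 ± 1651 and 6019 ± 4955, and the sinusoidal endothelial gene Stab2 at 2799 ± 1422, 1051 ± 162 and 805 ± 485. Krt19 of bile duct epithelium was at 109 ± 57.5, 42.6 ± 23.3 and 37.3 ± 12.2, Col1a1 of fibroblasts at 129 ± 145, 735 ± 483 and 679.5 ± 426, and the neutrophil gene S100a8 at 3.50 ± 6.07, 37.9 ± 43.5 and 17.4 ± 6.75. Without sham replicate 2 the sham means of Alb and Col1a1 were 2598 and 46.2, and S100a8 had 0 reads in the other sham libraries. The 2-week means were 466 for Col1a1 without 2-week replicate 1 and 12.9 for S100a8 without 2-week replicate 3. The 4-week means of Alb and Stab2 were 3869 and 535 without 4-week replicate 2, and that of Ptprc was 823 without 4-week replicate 1.

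Sham replicate 2 stood apart from all other libraries. Its correlations with them across genes lay between 0.741 and 0.828, against 0.855 to 0.957 for the 28 other pairs of libraries. The first principal component, with 41.7% of the variance, placed it at 134.6 and the others between −32.7 and 1.05. Its mean log2 level of the lymphatic endothelial identity list was 8.16, against 10.2 and 10.5 in the other sham libraries, and 1.37% of its normalized counts fell on mitochondrially encoded genes, against 0.527% and 0.742%. On the second component, 4-week replicate 1 lay at 67.1 and sham replicate 3 at the opposite end, at −55.6. The median correlation of 4-week replicate 1 with the other libraries was 0.891. It was 0.774 for sham replicate 2 and 0.888 for sham replicate 1, so 4-week replicate 1 did not stand apart in the same way. Counts of genes were also taken without sham replicate 2. A fit without sham replicate 2 and 4-week replicate 1 together was chosen after the data had been seen.

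**Figure D1:**
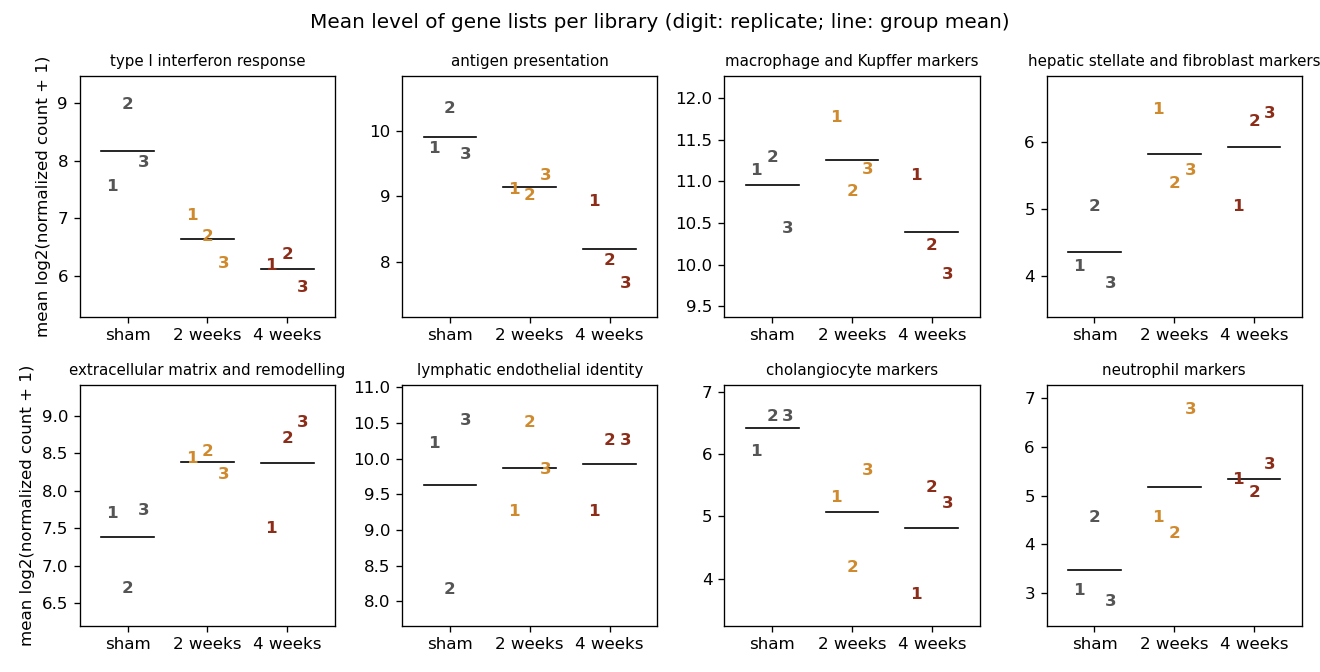
Mean log2(normalized count + 1) of 8 gene lists in each library, with digits marking the replicate and lines the group mean. Each panel has its own vertical axis. The interferon list was at 7.55 or above in each sham library and at 7.04 or below in each ligated library, while the lymphatic endothelial identity list was lowest in sham replicate 2.

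The first comparison asked how gene expression in the sorted cells differed 2 weeks after ligation. Serpina3n, an acute-phase serine protease inhibitor (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), rose from 52.3 ± 21.7 to 1224 ± 306 normalized counts (log2 fold change 4.58 ± 0.41 SE, limma, adjusted p = 0.00677, n = 3 per group). Chil3, a chitinase-like protein secreted by myeloid cells (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), rose as well (limma, adjusted p = 0.0139). It had 2 reads over the 3 sham libraries and 610 at 2 weeks, a ratio per recovered read of 165. The 95% exact interval, from 45.4 to 1364, covers counting error only. Both sham reads lay in sham replicate 1, so that without it the ratio has no finite value, and without sham replicate 3 it was 84.5. Serpina3n and Chil3 were the only 2 of 11809 genes to pass in limma, and each was higher in 3 of 3 ligated libraries than in any sham library. In edgeR 2 genes passed as well, Serpina3n and Ccr1, and Serpina3n was the 1 gene called by both tools. At an unadjusted p below 0.05 there were 1010 genes in limma and 1080 in edgeR, and DESeq2 called 211 genes at its adjusted p. With library quality weights limma called 1112 genes, 615 higher and 497 lower.

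Gene lists moved at 2 weeks as well. Of 35 lists tested with camera, 3 were shifted upwards and 8 downwards; none of these 11 kept its call with an estimated inter-gene correlation, where the lowest adjusted p was 0.424. The interferon response list fell by a median of 1.45 on the log2 scale with all 19 measured members lower (camera, adjusted p = 2.31e-19); none of them passed over all genes and 17 did when adjusted over the list alone. The RNA sensor gene Ddx58 stood at 289 in sham and 135 at 2 weeks, without passing over all genes. Antigen presentation genes had a median of −0.68, with 18 of 19 members below 0 (camera, adjusted p = 8.52e-09) and 0 passing when adjusted over the list alone. Cholangiocyte markers had a median of −1.58 (adjusted p = 3.10e-08, 13 of 15 lower, 9 adjusted over the list alone), and values of Pkhd1, a gene of the primary cilium, went from 374 to 79.9 (49.8 without 2-week replicate 3). In the opposite direction, stellate cell and fibroblast markers had a median of 1.45 (camera, adjusted p = 2.10e-06, 16 of 19 higher, 6 adjusted over the list alone) and extracellular matrix genes one of 0.57 (adjusted p = 5.27e-05, 24 of 27 higher, 6 adjusted over the list alone). The matrix median was 0.11 without sham replicate 2 and 0.89 without sham replicate 3. The collagen genes Col1a2 and Col5a1 stood at 46.8 and 17.8 in sham and at 434 and 156 at 2 weeks. Without 2-week replicate 1, in which both were highest, the 2-week means were 279.9 and 98.2. Neutrophil markers had a median of 2.16 over 6 members (adjusted p = 0.0206, 5 of 6 higher, 2 adjusted over the list alone), with Mmp8 at 1.13 in sham and 22.6 at 2 weeks. Mmp8 had 4 reads in sham, and without 2-week replicate 3 its 2-week mean was 13.3.

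Downward shifts at 2 weeks were found for 5 further lists. Unfolded protein response genes had a median of −0.50 (camera, adjusted p = 1.95e-05, 0 of 16 adjusted over the list alone), cholesterol synthesis and efflux genes −0.72 (adjusted p = 4.92e-05, 2 of 20), immediate early and dissociation stress genes −0.33 (adjusted p = 3.80e-04, 1 of 20), endothelial junction genes −0.36 (adjusted p = 0.00754, 1 of 19) and sinusoidal endothelial markers −0.67 (adjusted p = 0.0382, 2 of 15). None of these 5 passed with an estimated correlation (lowest adjusted p = 0.424), and of all 35 lists only the sinusoidal list passed in fry (adjusted p = 0.0326). The sinusoidal call was lost without sham replicate 1 or 2, 2-week replicate 1 or 4-week replicate 1 or 3 (medians −0.67, −0.02, −0.41, −0.67 and −0.67), the junction call without sham replicate 1 or 3 or 2-week replicate 1 (−0.15, −0.02 and −0.21), and the neutrophil call without sham replicate 1 or 3, 2-week replicate 3 or 4-week replicate 1 (1.71, 1.66, 1.13 and 2.16). The junction median was −0.60 without sham replicate 2, that of immediate early genes −0.51 without sham replicate 3 and that of unfolded protein response genes −0.33 without 2-week replicate 2. The calls of Serpina3n and Chil3 were both lost without 2-week replicate 2 or 3, where 0 genes passed, and that of Chil3 also without sham replicate 3. There were 10 passing genes without sham replicate 2, 14 without 4-week replicate 1 and 4 without sham replicate 1 (Serpina3n, Chil3, Ccr1 and Adam8). With sham replicate 2 and 4-week replicate 1 both left out there were 178.

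The second comparison asked the same question at 4 weeks of ligation, and here 142 of 11809 genes passed in limma, 63 higher and 79 lower than in sham. Ccr1, a chemokine receptor of myeloid cells (ENSMUSG00000025804, chromosome 9, 123962124 to 123968692), rose from 22.9 ± 11.8 to 420.3 ± 19.5 normalized counts (log2 fold change 4.28 ± 0.36 SE, limma, adjusted p = 0.00149, n = 3 per group). Serpina3n rose to 1481 ± 586 (log2 fold change 4.79 ± 0.41, adjusted p = 0.00149). Ciita, the master activator of MHC class II transcription (ENSMUSG00000022504, chromosome 16, 10480059 to 10528418), fell from 268 ± 48.2 to 34.9 ± 15.8 (log2 fold change −3.01 ± 0.39, adjusted p = 0.0105).

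**Figure D2:**
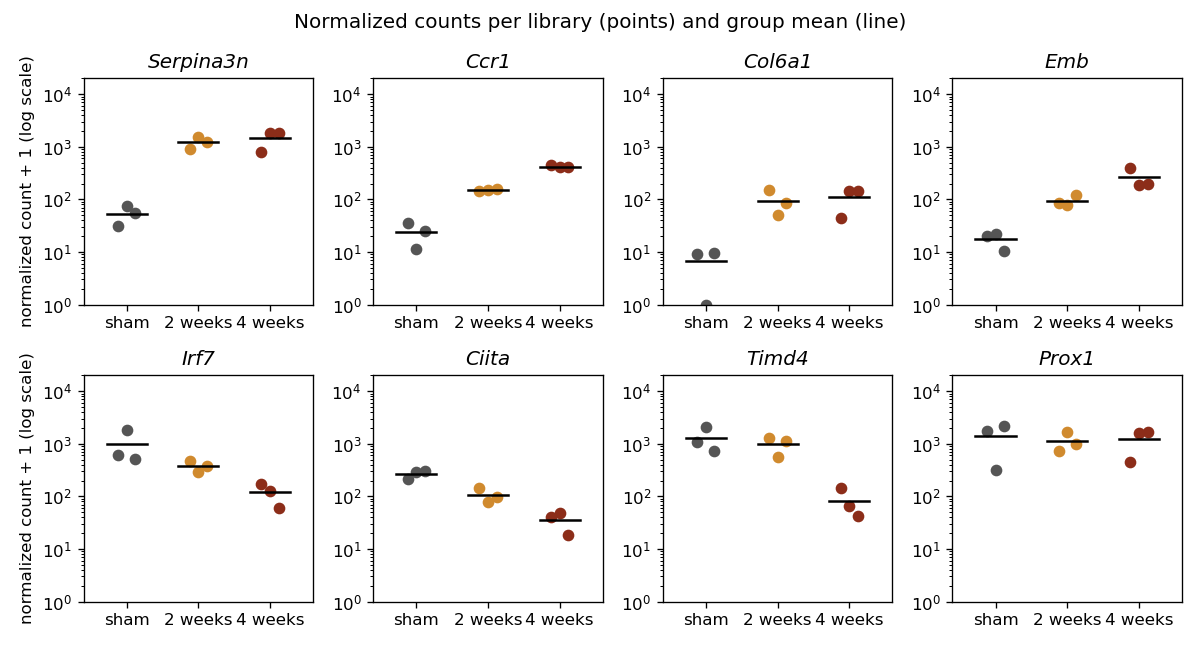
Normalized counts plus 1, on a log scale, of 8 genes in the 3 sham, 3 2-week and 3 4-week libraries, with points for libraries and lines for group means. Serpina3n, Ccr1, Col6a1 and Emb were higher at 4 weeks than in sham, Irf7, Ciita and Timd4 were lower, and Prox1 ranged widely within each group.

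Among the genes with the largest rises, Chil3 had 2457 reads at 4 weeks against 2 in sham, a ratio of 970 with a 95% exact interval from 268 to 8014 (limma, adjusted p = 0.00149). It rests on the same 2 reads of sham replicate 1 and was 498 without sham replicate 3. Adam8, a metalloprotease of leukocytes, rose with a log2 fold change of 5.03 ± 0.65 (limma, adjusted p = 0.0105), and Col6a1, a chain of collagen VI, with 4.44 ± 0.87 (adjusted p = 0.0418). Slc7a11, the cystine and glutamate exchanger, rose from 38.4 to 668 and Emb, which encodes embigin, from 16.5 to 261. Slit3, a secreted guidance ligand, rose from 5.98 to 97.4, Gda, which encodes guanine deaminase, from 73.1 to 996, and Pf4, the chemokine platelet factor 4, from 29.9 to 279.6. The log2 fold changes of these last 5 genes lay between 3.70 and 3.92, and their adjusted p in limma between 0.00471 and 0.0295. Without sham replicate 2 the log2 fold changes of Adam8, Col6a1 and Pf4 were 4.21, 3.37 and 2.81, all called, and the sham mean of Slit3 was 3.71. Without sham replicate 1 the log2 fold changes of Adam8 and Pf4 were 5.84 and 4.44, and without 4-week replicate 1 the 4-week mean of Gda was 642. Among the genes with the largest falls, the interferon-induced genes Gbp2b, Ifi206, Ifi27l2a and Gbp4 changed by log2 fold changes of −5.22, −4.06, −3.87 and −3.35. Their sham levels, 547 ± 575, 169 ± 163, 230.2 ± 247 and 1214 ± 1050.0 normalized counts, were highest in sham replicate 2. Without that library the log2 fold changes were −4.38, −3.32, −3.02 and −2.69, all called. Timd4, a phosphatidylserine receptor of resident macrophages (ENSMUSG00000055546, chromosome 11, 46810800 to 46844332), fell from 1312 ± 721 to 82.2 ± 52.0 (log2 fold change −4.02 ± 0.53, limma, adjusted p = 0.0105). Its 4-week mean was 52.98 without 4-week replicate 1. Gfra2, Il12b, Kcna2, Tlr12 and Shank2 fell with log2 fold changes of −3.96, −3.84, −3.46, −3.41 and −3.39, Il12b encoding the p40 subunit of interleukin-12. These folds are on the log2(normalized count + 1) scale, where the added 1 shrinks changes of low genes. They are differences of mean logs, so a sham library near 0 can also enlarge them. Sham replicate 2 had 2, 0 and 1 reads of Adam8, Col6a1 and Pf4, whose folds were smaller without it.

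The interferon response list fell at 4 weeks. All 19 measured members were lower, the list's median fell by 2.12 on the log2 scale (camera, adjusted p = 3.72e-21; adjusted p = 0.451 with an estimated correlation), 6 members passed over all genes and 18 adjusted over the list alone. The mean log2 level of the list was 8.16 ± 0.73 in sham, 6.64 ± 0.42 at 2 weeks and 6.11 ± 0.30 at 4 weeks, with the highest value, 8.98, in sham replicate 2, and without that library the median was −1.40 and still called. Irf7, which drives interferon production, fell from 969 to 119, with a sham mean of 555 without sham replicate 2. Ddx58 fell from 289 to 102 and Bst2, the antiviral tetherin, from 215 to 71.6. All 19 antigen presentation genes were lower as well, with a median of −1.48 (camera, adjusted p = 3.72e-20; adjusted p = 0.451 with an estimated correlation), 4 of them passing over all genes and 18 adjusted over the list alone. The MHC class II genes H2-Aa and H2-Eb1 fell from 3993 and 4273 to 755 and 624, and Psmb9, a subunit of the immunoproteasome, from 101 to 34.6. The log2 fold change of H2-Aa, −2.79, was −3.52 without 4-week replicate 1 and −2.18, no longer called, without 4-week replicate 3. That of H2-Eb1, −3.08, was −3.75 without 4-week replicate 1. In fry the interferon list passed with adjusted p = 0.0363 and the antigen presentation list with adjusted p = 0.0443. The mean log2 level of macrophage and Kupffer markers was 10.95 ± 0.46 in sham, 11.26 ± 0.46 at 2 weeks and 10.39 ± 0.61 at 4 weeks.

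Members of the macrophage and Kupffer list went both ways at 4 weeks. The list as a whole shifted downwards (median −0.66, camera, adjusted p = 0.00943; adjusted p = 0.875 with an estimated correlation), 2 of 17 members passed over all genes, both lower, and adjusted over the list alone 4 were lower and 2 higher. Clec4f fell from 10215 ± 3463 to 1109.7 ± 601 (log2 fold change −3.30 ± 0.56, limma, adjusted p = 0.0268). Gpnmb, a glycoprotein of lipid-laden macrophages, was at 478 ± 433 in sham and 6164 ± 2382 at 4 weeks without passing over all genes (limma, adjusted p = 0.0560). Its sham mean was 263 without sham replicate 1. The list's call was lost without sham replicate 2, where its median was −0.23, and without 4-week replicate 2 or 3, with medians of −0.61 and −0.43.

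Stellate cell and fibroblast markers had a median of 1.76 (camera, adjusted p = 6.78e-06; adjusted p = 0.625 with an estimated correlation), with 16 of 19 members higher, 0 passing over all genes and 8 adjusted over the list alone. Extracellular matrix genes had a median of 0.64 (camera, adjusted p = 0.00101; adjusted p = 0.875 with an estimated correlation), 2 of 27 passing over all genes and 6 adjusted over the list alone. Those 2 were Col6a1 and the gelatinase gene Mmp2, which rose from 16.5 to 94.1. The matrix list's call was lost without 4-week replicate 3, where its median was 0.41; the median was 0.11 without sham replicate 2 and 0.96 without 4-week replicate 1, both called. Cholangiocyte markers had a median of −1.79 (camera, adjusted p = 1.96e-07; adjusted p = 0.625 with an estimated correlation), with 14 of 15 members lower, 0 passing over all genes and 11 adjusted over the list alone; Pkhd1 was at 374 in sham and 56.2 at 4 weeks. Downward shifts were also found for chemokine and leukocyte adhesion genes (−0.37, camera, adjusted p = 0.0180, 1 of 22 adjusted over the list alone), immediate early and dissociation stress genes (−0.39, adjusted p = 8.32e-04, 2 of 20), unfolded protein response genes (−0.33, adjusted p = 0.0180, 0 of 16) and cholesterol synthesis and efflux genes (−0.50, adjusted p = 0.00160, 0 of 20). Hspb1, a small heat shock protein, was the 1 member of these 4 lists to pass over all genes, falling from 242 to 79.9. With an estimated correlation these lists had adjusted p between 0.625 and 0.875. The calls of the chemokine and unfolded protein response lists were lost without sham replicate 2 (−0.32 and −0.21) and without 4-week replicate 2 (−0.30 and −0.38), and that of the immediate early list without 4-week replicate 2 (−0.21). Medians were more negative without sham replicate 3 for the first pair (−0.61 and −0.55) and without 4-week replicate 1 for chemokine and immediate early genes (−0.63 and −0.70). Outside the lists moved at 4 weeks, Vegfa rose from 419 to 1300.5 and Fcgr2b, an inhibitory Fc receptor, from 159 to 526, while Dnase1l3 fell from 232 to 31.4, Ocln, a tight junction gene, with a log2 fold change of −2.43 ± 0.39 and Ankrd1, a target of YAP, from 118 to 16.4.

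edgeR called 167 genes at 4 weeks, 75 higher and 92 lower, of which 134 were also called by limma, and DESeq2 called 573. With library quality weights limma called 1608, 773 higher and 835 lower. The number of calls in limma depended on single libraries. It was 9 without 4-week replicate 3, 38 without 4-week replicate 2, 68 and 70 without sham replicates 3 and 1, and 74 without 2-week replicate 3. Without sham replicate 2 it was 173 (105 higher, 68 lower, 110 of them among the 142). With sham replicate 2 and 4-week replicate 1 both left out it was 467. Chil3, Serpina3n, Ccr1, Emb, Gda and Ciita kept their 4-week calls in each of 23 alternatives. Reads on 1454 olfactory and vomeronasal receptor genes made up 0.00373%, 0.0442% and 0.00522% of the recovered reads of sham replicates 1, 2 and 3. They made up 0.0279%, 0.00847% and 0.0196% at 2 weeks and 0.0217%, 0.0686% and 0.140% at 4 weeks. Of the 63 genes called higher at 4 weeks, 8 were predicted gene models, against 1 of the 79 called lower. Of 42 calls of named genes at 2 or 4 weeks, 26, 37 and 22 were kept without sham replicates 1, 2 and 3, 36, 34 and 26 without 2-week replicates 1, 2 and 3, and 30, 14 and 10 without 4-week replicates 1, 2 and 3.

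The third comparison set 4 weeks of ligation against 2 weeks, and no single gene passed. In limma 0 genes passed, with 475 at an unadjusted p below 0.05, and in edgeR 0 passed, with 547. DESeq2 called 78 genes, and limma with library quality weights 349. The gene nearest the threshold was Slc16a9, a carnitine transporter, at 169 ± 31.9 at 2 weeks and 39.4 ± 3.59 at 4 weeks (log2 fold change −2.05 ± 0.24 SE, limma, adjusted p = 0.0739, n = 3 per group). Timd4 was at 987 ± 384 and 82.2 ± 52.0 (adjusted p = 0.241 in limma), Gbp2b at 172 and 9.75, Kcnj16 at 138 and 13.9 and Epb41l3 at 523 and 125. In the other direction, with log2 fold changes that did not pass either, were Plxnc1 (1.31), Pde4d (1.42), Vegfa (1.13), Eps8 (1.23) and Slc16a1 (1.39). Without sham replicate 2, which is in neither group of this contrast, 11740 genes were tested and 2 genes passed, Slc16a9 and Gbp2b, both lower at 4 weeks. With sham replicate 2 and 4-week replicate 1 both left out 203 passed, 23 higher and 180 lower.

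Of the 35 lists, 6 moved between 2 and 4 weeks. Antigen presentation genes were lower at 4 weeks in 19 of 19 members (median −0.82, camera, adjusted p = 4.56e-18; adjusted p = 0.359 with an estimated correlation; 1 adjusted over the list alone). Macrophage and Kupffer markers had a median of −0.59 (camera, adjusted p = 8.50e-07; adjusted p = 0.877 with an estimated correlation; 5 of 17 lower adjusted over the list alone), and interferon response genes one of −0.40 (adjusted p = 1.17e-05; adjusted p = 0.877 with an estimated correlation; 1 of 19). Sinusoidal endothelial markers (0.54, camera, adjusted p = 0.0311; adjusted p = 0.359 with an estimated correlation), blood vascular endothelial markers (0.58, adjusted p = 0.00198; adjusted p = 0.359 with an estimated correlation) and glycolysis and hypoxia genes (0.22, adjusted p = 0.0311; adjusted p = 0.877 with an estimated correlation) shifted upwards, with 3, 0 and 0 members passing when adjusted over the list alone. The blood vascular call was lost without 4-week replicate 3 (median 0.31), the glycolysis call without 2-week replicate 2 or 4-week replicate 1 (0.17 and 0.23), and the sinusoidal call without 2-week replicate 1 or any of 4-week replicates 1, 2 and 3 (0.14, 0.84, 0.51 and 0.37). Among lists that stayed called, the macrophage median was −0.39, −0.94 and −0.31 without 2-week replicate 1, 4-week replicate 1 and 4-week replicate 3, the interferon median −0.68 without 2-week replicate 3, the sinusoidal median 0.86 without 2-week replicate 2 and the blood vascular median 0.99 without 4-week replicate 1. Without 4-week replicate 1 there were 14 moved lists, and without 2-week replicate 3 there were 10.

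Of the 35 lists, 20 moved in none of the 3 contrasts. They were lymphatic endothelial identity, lymphatic valve and collector genes, pan-endothelial genes, hepatocyte and dendritic cell markers, the sphingosine-1-phosphate pathway, lymphangiogenic and angiogenic signalling, cell cycle, TGF-beta and mesenchymal transition, fatty acid uptake and oxidation, nuclear-encoded and mitochondrially encoded respiratory genes, NF-kB and inflammatory response, bile acid receptors and transporters, NRF2 and oxidative stress, p53 targets and senescence, Notch, shear stress and YAP targets, nitric oxide and vasoactive mediators, and cytosolic ribosomal proteins. Their lowest adjusted p in camera was 0.134 at 2 weeks, 0.0631 at 4 weeks and 0.0566 between 4 and 2 weeks. Median, mean and camera's direction differed in sign for 5, 7 and 7 of the 35 lists in the 3 contrasts, none of them called. The calls depended on sham replicate 2: without it 21 lists moved at 2 weeks and 19 at 4 weeks. The lymphatic endothelial identity list, with medians of 0.16 at 2 weeks and 0.35 at 4 weeks, was then called lower at both times (−0.52 and −0.51). Pan-endothelial genes (−0.76 and −0.56), lymphatic valve and collector genes (−0.47 and −0.53) and dendritic cell markers (−0.88 and −1.10) were called lower as well, and hepatocyte markers (1.17 and 1.63) and cytosolic ribosomal proteins (0.32 and 0.47) higher. The hepatocyte list, with medians of 0.45 and 0.98 over all libraries, was called lower at 2 weeks without sham replicate 1 (−0.64) and higher at 4 weeks without 4-week replicate 1 (2.00).

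The fourth comparison asked how far the responses at 2 and 4 weeks resembled each other. All 63 genes that rose at 4 weeks were also higher at 2 weeks than in sham, 59 of them at an unadjusted p below 0.05 in limma, with a median log2 fold change of 3.22 at 4 weeks and 2.32 at 2 weeks. Of the 79 genes that fell, 76 were lower at 2 weeks too, 47 of them at an unadjusted p below 0.05, with medians of −2.29 and −0.89. In 100 simulations of unchanged groups, the 63 genes with the lowest p and higher at 4 weeks were also higher at 2 weeks for 61.0 on average (57 to 63), at an unadjusted p below 0.05 for 51.0 on average (41 to 58). The 79 lower ones were lower for 76.6 on average (73 to 79), at an unadjusted p below 0.05 for 65.8 on average (57 to 72). The counts by direction, 63 and 76, thus lay within the simulated ranges, whereas 59 lay above its range and 47 below. Genes were simulated as independent, whereas genes of these libraries vary together, so the ranges are likely too narrow. The places of 59 and 47 outside them therefore decide nothing. Both genes called at 2 weeks, Serpina3n and Chil3, were also called at 4 weeks. Across the 11809 genes, which are not independent replicates, the fold changes correlated with r = 0.839 and 81.0% had the same sign. Unchanged groups set against the same sham libraries gave r = 0.722 and 71.2% on average over 100 simulations. The covariance was 0.504, against 0.274 in the simulations (0.253 to 0.309), a difference of 0.229. Genes were independent in these simulations too, so this range is likely too narrow as well. With 3 sham libraries the controls could not be split into parts of at least 2 libraries, and part of the excess may come from the shared controls.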

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

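The fit with the macrophage covariate and the tests of the interferon list with each library left out and of Kupffer markers at 2 weeks were chosen after the data had been seen. The lists named here were picked out because their response differed between 2 and 4 weeks of ligation by a test of the difference itself. Median log2 differences, 4 weeks minus 2 weeks, were −0.82 for antigen presentation, −0.59 for macrophage and Kupffer markers, −0.40 for type I interferon response, 0.54 for sinusoidal endothelial markers, 0.58 for blood vascular endothelial markers and 0.22 for glycolysis and hypoxia. No such difference passed with an estimated inter-gene correlation.

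The fall of interferon response genes at 4 weeks was weighed first. If it came from fewer macrophages among the sorted cells, it should shrink to less than 0.5 times its size once the macrophage marker level is held constant. The list's median with that level as a covariate was −1.77, against −2.12 without it. This decides nothing, since 4 of the 17 members of the macrophage list were higher and 13 lower at 4 weeks, and their mean does not hold the share of resident macrophages constant. No single library carried the fall alone: the median nearest 0 was −1.40, reached without sham replicate 2, in which the list was highest. At 2 weeks the interferon list already had a median of −1.45, while resident Kupffer markers had one of 0.16, at the lowest −0.15 with 1 library left out, and the difference exceeded the SD of the Kupffer members each time. This decides nothing either, since 6 of the 10 Kupffer members were higher and 4 lower at 2 weeks. Their median then does not measure the share of resident macrophages. RNA of fewer resident macrophages therefore stays open for the part of the fall present at 2 weeks. It stays open for the further fall to 4 weeks as well, where Kupffer markers had a median of −1.70. A change in the interferon response of some cells during ligation, or a high response in the sham mice, stays open, and which cells carried it was not tested.

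Sham replicate 2 was weighed next. With all libraries thinned to 592419 reads, its median correlation with the others was 0.804, against 0.869 to 0.900 for the other 8 libraries (SD 0.0118), so shallow depth alone does not account for its distance. Of the genes with at least 20 expected reads, 0.145% were at 0 in it, against 0 to 0.260% in the other thinned libraries, so a loss of distinct RNA molecules was not seen by this measure. Its transcripts were poorer in endothelial genes. The mean log2 level of the pan-endothelial list was 7.41, against 9.21 and 9.51 in sham replicates 1 and 3. That of macrophage and Kupffer markers was 11.3, against 11.1 and 10.4. Whether this came from a different mixture of sorted cells stays open and was not tested. Since the pattern is in 1 library, the design offers no biological explanation to test.

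Beyond these lists, other splits of the 6 libraries of each contrast were run, the remaining group kept as it was. At 2 weeks the real grouping gave 2 genes, at 4 weeks 142, and between 4 and 2 weeks 0; the highest of the other 9 splits gave 0 in each case. Thus 1, 1 and 10 of the 10 splits gave as many genes as the real one. With 10 splits no share under 0.05 can be reached.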

How the results depend on the processing

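Without any alternative, limma called 2 genes at 2 weeks (2 higher, 0 lower), 142 at 4 weeks and 0 between them, and camera moved 11, 10 and 6 lists. Of 42 calls of named genes at 2 or 4 weeks, 42 were kept under library quality weights and DESeq2, 38 in edgeR, 28 with the macrophage covariate and 10 without 4-week replicate 3; no called gene changed direction under any alternative. Of 27 list calls, 27 were kept with pseudocounts of 0.5 and 5 and with TMM, 24 with quantile normalization, 4 in fry and 0 with an estimated correlation. Among values called neither way, 179 of 10616 for genes and 196 of 2301 for lists had another sign than in the fit reported. The fits chosen after seeing the data were those with the macrophage covariate, without sham 2 and 4-week 1 together, and edgeR without sham 2. The cause of the differences below was not tested, except that leaving out libraries or groups leaves fewer samples for the spread.

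Gene counts at 2 weeks, 4 weeks and between them were 1112, 1608 and 349 with library quality weights and 211, 573 and 78 in DESeq2. They were 178, 467 and 203 with both libraries, sham replicate 2 and 4-week replicate 1, left out. Quantile normalization gave 14 (12 higher, 2 lower) and 259, and a fit of only the 2 groups compared 1 and 53. The covariate gave 4 at 2 weeks (Serpina3n, Chil3, Ccl6 and Clca3a1). Between 4 and 2 weeks a minimum mean of 50 gave 1, Slc16a9, and edgeR without sham 2 gave 2, Slc16a9 and Gbp2b. Leaving out 1 library gave 0 to 14, 9 to 173 and 0 to 2.

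The replicate numbers showed no clear pairing of the samples: 2 of 9 same-numbered pairs had deviations correlating over 0.1 (−0.445 to 0.228), and for 3 of 9 the best match had the same number. With so few libraries this cannot show that there was none, and the labels do not say. With the number as a block 84 genes passed at 4 weeks, 2 at 2 weeks and 0 between them.

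List counts were 0, 0 and 0 with an estimated correlation, 1, 2 and 1 in fry, and 18, 20 and 14 without both libraries. Quality weights gave 16 at 4 weeks and 14 between 4 and 2 weeks, and the covariate 16 between 4 and 2 weeks, the macrophage list left out of the count. Leaving out 1 library gave 9 to 21, 8 to 19 and 5 to 14. The correlation of the 2-week and 4-week fold changes was 0.700 without both libraries, 0.671 with the covariate and 0.724 to 0.883 with 1 library left out.

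Lists turned direction as follows. With 1 library left out, the lymphatic identity median ranged from −0.52 to 0.70 at 2 weeks and −0.51 to 0.82 at 4 weeks, that of nuclear-encoded oxidative phosphorylation from −0.19 to 0.13 and −0.19 to 0.29, the ends turned being those without sham replicate 2, and that of hepatocyte markers at 2 weeks from −0.64, without sham replicate 1, to 1.17. Without both libraries, lymphatic identity had −0.52 at 2 weeks, and at 4 weeks oxidative phosphorylation had 0.28 and mitochondrially encoded transcripts 0.24. The latter had 0.35 at 4 weeks with quality weights. With the covariate, lymphatic identity had −0.45 at 4 weeks. Between 4 and 2 weeks the covariate gave −1.16 for it, −1.04 for pan-endothelial, −0.62 for junction, −0.88 for matrix, 0.43 for NF-kB and 0.41 for immediate early genes; blood vascular markers turned in camera with a median of 0.25. Depth limits low genes most in sham replicate 2.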

Other observations

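The macrophage lists reported here and the tests on them were chosen after the fall of Timd4 and the rise of Chil3 had been seen. Their p values were adjusted over these 3 lists alone. They are therefore less strict than those of the 35 lists above and cannot be set beside them. Resident Kupffer markers had a median log2 fold change of 0.16 at 2 weeks (camera, adjusted p = 0.596) and −1.70 at 4 weeks (adjusted p = 3.16e-08; adjusted p = 0.0877 with an estimated correlation), with 9 of 10 members below 0 at 4 weeks. Of these 10 genes, 5 also stand in the macrophage and Kupffer list above, as do 2 of 10 scar-associated genes and 0 of 12 monocyte genes. Between 2 and 4 weeks all 10 members were lower, with a median of −1.81 (adjusted p = 8.39e-22; adjusted p = 0.0403 with an estimated correlation). Cd5l, a secreted protein of resident macrophages, was at 10243 in sham, 8031 at 2 weeks and 2069 at 4 weeks, and Marco, a scavenger receptor, at 1671, 8061 and 888; without sham replicate 2 the sham means were 6653 and 969, and without 4-week replicate 1 the 4-week mean of Marco was 559.6. Markers of monocytes and recruited macrophages had medians of 1.79 at 2 weeks (camera, adjusted p = 1.22e-04; adjusted p = 0.0469 with an estimated correlation), 1.14 at 4 weeks (adjusted p = 0.00281; adjusted p = 0.0877 with an estimated correlation) and 0.09 between them (adjusted p = 0.590). Scar-associated macrophage markers had medians of 0.54, 0.85 and 0.53 (camera, adjusted p = 0.00771, 5.85e-05 and 3.03e-04; adjusted p = 0.260, 0.0877 and 0.129 with an estimated correlation), and 1 of 9 members, Fabp5, passed at 4 weeks, rising from 129.6 to 675.

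The mean log2 level of the monocyte list minus that of the Kupffer list lay between −7.11 and −5.78 in sham, −5.96 and −4.91 at 2 weeks and −3.77 and −2.98 at 4 weeks. It changed by 1.295 at 2 weeks (exact permutation test, two-sided p = 0.2) and by 3.17 at 4 weeks (p = 0.1, the smallest that 3 against 3 libraries can give). A rise or fall of macrophages as 1 population would move both lists alike. The change at 4 weeks was at least 2.91 whichever library was left out. It was at least 2.46 without the Kupffer markers called at 4 weeks, Clec4f and Timd4. These values do not exclude such a rise or fall, since the lists were chosen after Timd4 and Chil3 had been seen to move. A comparison with 10000 pairs of random lists matched on sham level decides nothing, since the lists were chosen after some of their genes had been seen to move; the random lists parted by a median of 0.917 and by 2.31 at most, and 0 of them reached the change seen. At 4 weeks 8 of 10 tested monocyte markers were higher and 2 lower, and none passed over all genes. Of the 12 genes in the monocyte list, only these 10 reached the minimum mean. Ly6c2 had 2, 6 and 3 reads in 4-week replicates 1, 2 and 3 and S100a4 had 0, 0 and 2, too few to be tested. Which cells the transcripts that rose came from was not tested. Plac8 went from 145.6 in sham to 71.1 (44.9 without sham replicate 2, 24.7 without 4-week replicate 1). Ccr2 went from 18.1 to 26.9 (27.1 without sham replicate 2, 14.4 without 4-week replicate 2). A candidate explanation is that the macrophages whose RNA entered the libraries changed in kind during ligation, from resident towards recruited cells. It was not tested, and single monocyte markers do not settle it. A change of expression within resident cells stays equally open, as does how macrophage RNA came into a sort for lymphatic endothelium.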
